A study of Mus musculus with 8 samples.

How the data were processed

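The libraries hold RNA from antigen-specific mouse CD4 T cells, either helper cells of the B cell follicle (Tfh) or other activated helper cells (non-Tfh), carrying a Bach2 vector or an empty vector. Per the labels, the cells came from Smarta mice, whose T cells carry 1 transgenic receptor for a viral peptide, crossed to a line with a tamoxifen-activated Cre recombinase. They were transduced with an inducible retroviral vector, transferred to C57BL/6 hosts and activated by immunization under the skin with the receptor's peptide on a serum albumin carrier. Per the labels, tamoxifen was given on day 5 and cells were taken from pooled groin lymph nodes 18 hours later, on day 6. Sorting was on Thy-1.1 and high CD44, with CXCR5 and PD-1 both present (Tfh) or both absent (non-Tfh). Per the labels' protocols, RNA was purified with a micro-scale column kit, amplified with Smart-Seq v4, made into libraries with Nextera XT and sequenced in pairs on a NextSeq500. This kit does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

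The deposited values are counts, 1 whole number per Ensembl gene and library, as the values themselves show (no decimals, and totals that differ between libraries). Per the submitters' processing notes, reads were handled with TopHat2, Bowtie2 and featureCounts on the GRCm38/mm10 mouse genome. Versions, the annotation release, and the handling of reads that match several places are not given in the sources used here. Genes with close copies, such as H2-Q2, Ifi204, Ly6c2, Ccl3, Ccl4 and the granzymes, are therefore uncertain in how their reads were split. The files list 39179 genes. Gene symbols and GRCm38 positions were taken from the GENCODE M21 annotation by Ensembl ID, which matched 37607 IDs. The other 1572 IDs held between 0.187% and 0.205% of the counts of a library and stayed in the fit under their IDs.

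Library totals ran from 7862879 counts (Tfh cells with empty vector, replicate 2) to 9889859 counts (Tfh cells with empty vector, replicate 1). Between 14689 and 15167 genes had at least 1 count. A floor of 3 counts, the upper limit that a count of 0 allows at 95% confidence, was 0.303 to 0.382 CPM (counts scaled to the size of each library). Where a group pooled 1 to 3 counts, the ratio to the other group is given with its exact 95% counting interval, and where it pooled 0 counts a bound was computed against 3 counts over the group. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. CPM values were scaled with trimmed mean of M-values (TMM) factors, which ran from 0.985 to 1.01.

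The 8 libraries form 4 groups of 2. The labels do not state whether replicates are separate animals or cultures, so the p-value of a gene measures only the spread between these samples. Comparisons were Bach2 against empty vector in Tfh cells, the same in non-Tfh cells, Tfh against non-Tfh cells with empty vector, the same with the Bach2 vector, and the interaction (the vector effect in Tfh cells minus that in non-Tfh cells). Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 11475 genes. Counts were fitted over all 8 libraries with 1 coefficient per group, which leaves 4 residual degrees of freedom, using edgeR 4.0.16 in R 4.3.3. The robust quasi-likelihood test was used with Benjamini-Hochberg adjustment over the tested genes, and adjusted p below 0.05 counted as past the threshold. The common dispersion was 0.00979, a biological coefficient of variation of 9.89%, and the median prior degrees of freedom were 9.90. An exact test of 2 libraries against 2 cannot go below p = 0.333 (two-sided), so single genes were tested only in this model. A multidimensional scaling was computed from the same filtered values with edgeR's defaults and a prior count of 2. A chi-square per degree of freedom between the replicates of a group was computed to check for copied libraries.

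Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated from the data and fry, which tests a list by itself, were run beside it. At the preset correlation the p-value sets list members against other genes, so it does not measure the spread between libraries. With an estimated correlation camera rests on the 4 residual degrees of freedom and can miss real shifts. For the heme and oxidative stress list (vector effect, Tfh cells) the estimated correlation was -0.0244, below the preset. Its unadjusted camera p still went from 0.000780 to 0.0209. Of 39 lists, 37 had at least 5 tested members. The lists were Tfh programme, Th1 and effector programme, naive and memory programme, reported Bach2-repressed genes, AP-1 and Maf family factors, T cell receptor (TCR)-induced early response, costimulatory and inhibitory receptors, chemokine and migration receptors, and cytokine receptors and signalling. Further lists were Th2 genes, Th17 genes, Treg and Tfr genes, DNA replication, mitosis, cell cycle inhibitors and arrest, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, amino acid transport and mTORC1, Myc and ribosome biogenesis, and interferon response. The others were apoptosis and Bcl2 family, p53 response, heme and oxidative stress response, chromatin and cytosine modifiers, and T cell identity, then markers of B cells, plasma cells, MHC class II presentation, myeloid cells, CD8 T cells and NK cells. The set closed with dissociation and heat shock response, mitochondrially encoded genes, cytosolic ribosomal proteins and histone genes. Stromal and erythroid markers had too few tested members and are given as summed CPM. Lists share members, so their tests are not independent.

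The comparisons, the lists, the test settings and the rule for named genes were fixed before the data were examined. The rule names Bach2 in every library. In each comparison it names up to 8 genes with the largest rise and 8 with the largest fall among genes past the threshold, with at least 10 CPM in the higher group, no overlap between the libraries of the groups compared, and a symbol that is no predicted model, pseudogene or receptor segment. For the interaction, where none passed, it names the 4 genes with the smallest unadjusted p in each direction. It adds a core panel of 26 genes of helper T cell identity and, from each list described, at most 4 members with the smallest adjusted p. Cxcr5, Pdcd1 and Cd44 encode proteins used in the sorting gate and count as no finding between Tfh and non-Tfh cells. A few genes that the rule chose are not reported here, and counts of genes still include them.

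The alternatives tried were DESeq2-style (RLE) and upper quartile scaling, no filter beyond 1 count, at least 10 CPM in 2 libraries, a non-robust fit, the replicate number as a block, only the groups compared, a test against a 1.5-fold change, leaving out genes of other cell types and Bach2, DESeq2 1.42.0, limma-voom, and leaving out each of the 8 libraries. With a library left out, the lone library of its group is assumed to vary like the other groups. The list tests without gate genes or without members shared between lists were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

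The gene test was tested on simulated data made from each gene's mean over the groups, its estimated dispersion and the library sizes, with 50 genes changed in 1 group at each fold. For Bach2 against empty vector in Tfh cells (11240 genes), it called 56% of genes changed by 1.5-fold, 68% at 2-fold, 80% at 3-fold and 88% at 4-fold, and 12 of 158 calls were false. For the same comparison in non-Tfh cells (11263 genes) the shares were 52%, 72%, 92% and 88%, with 19 of 171 calls false. For Tfh against non-Tfh cells with empty vector (11254 genes) they were 42%, 64%, 78% and 90%, with 12 of 149 false, and with the Bach2 vector (11269 genes) 44%, 64%, 80% and 94%, with 7 of 148 false. For the interaction (11276 genes) they were 12%, 54%, 70% and 70%, with 12 of 115 false. In 4 of these 5 simulations the share of false calls lay above the 5% that the threshold aims at. No library was left out of the fits reported first. Splits of the samples into other groups were not counted, since each group holds 2 libraries.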

Results

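Cell type set the largest difference among the 8 libraries, and the vector the next. On the first axis of a multidimensional scaling, which held 67.4% of the variation, Tfh libraries lay from -1.49 to -1.08 and non-Tfh libraries from 1.17 to 1.40. The second axis (9.02%) ran from -0.557 to -0.361 for empty vector libraries and from 0.207 to 0.729 for Bach2 libraries. The mitochondrial share of counts was 0.902 ± 0.0604% in non-Tfh cells with empty vector, 0.965 ± 0.0299% in non-Tfh cells with Bach2, 1.03 ± 0.105% in Tfh cells with empty vector and 1.17 ± 0.123% in Tfh cells with Bach2 (SD, n = 2). The 10 genes with most counts held 7.06% to 8.30% of a library. The replicates of a group were not copies of each other, and differed by a chi-square per degree of freedom of 5.98 to 9.36.

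Bach2, which encodes a transcription repressor that restrains effector differentiation of lymphocytes, rose with its vector in both cell types. In Tfh cells it went from 12.6 ± 1.99 to 127.8 ± 9.85 CPM (SD, n = 2), and in non-Tfh cells from 26.9 ± 2.87 to 144.0 ± 19.1 CPM. The log2 fold changes were 3.35 (SE 0.149, adjusted p = 2.86e-08) in Tfh and 2.42 (SE 0.136, adjusted p = 6.57e-07) in non-Tfh cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The vector added 115 CPM (SE of the difference 7.10) in Tfh cells and 117 CPM (SE 13.7) in non-Tfh cells. With empty vector, Bach2 was lower in Tfh than in non-Tfh cells (-1.10, SE 0.157, adjusted p = 0.000168), and with the Bach2 vector that difference was not past the threshold (-0.17, SE 0.122, adjusted p = 0.347). Counts of Bach2 (chromosome 4, 32238804 to 32586108) hold vector and endogenous transcripts, which cannot be told apart here.

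**Figure D1:**
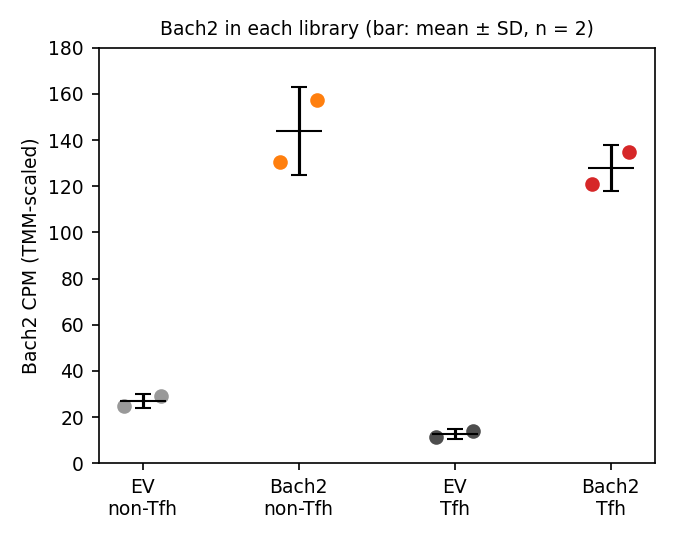
Bach2 expression in each library, in CPM scaled with TMM factors (y axis), for the 4 groups (x axis). Points are libraries and bars are means ± SD, n = 2 per group, with means of 12.6 and 127.8 CPM in Tfh cells and 26.9 and 144.0 CPM in non-Tfh cells (empty vector, then Bach2).

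In Tfh cells with the Bach2 vector, 30 of 60 mitosis genes and 20 of 44 DNA replication genes fell, and 7 of 31 naive and memory genes rose. As lists these were past the threshold at camera's preset correlation, with adjusted p = 0.196, 0.187 and 0.187 with an estimated correlation. Tigit, an inhibitory receptor, fell from 377 ± 36.8 to 188 ± 13.5 CPM (SD, n = 2), with a log2 fold change of -1.003 (SE 0.115, adjusted p = 0.00183). Cdc6, which loads the replicative helicase (chromosome 11, 98907801 to 98923940), fell from 36.8 ± 2.86 to 15.8 ± 2.97 CPM (-1.22, SE 0.156, adjusted p = 0.00339). Lef1, a transcription factor of naive and early Tfh cells, rose from 316 ± 11.1 to 456 ± 22.1 CPM (0.53, SE 0.0900, adjusted p = 0.0112). Bcl6, the factor that defines Tfh cells, was 147 ± 17.3 CPM with empty vector and 111 ± 13.0 CPM with Bach2, a change not past the threshold (-0.41, adjusted p = 0.114). Over all 11475 genes, 63 rose (Bach2 among them) and 133 fell, and 22 of these changed at least 2-fold.

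The largest rises after Bach2 were in Scml4, a Polycomb-related gene (chromosome 10, 42860370 to 42960780), from 9.71 ± 0.312 to 23.3 ± 8.39 CPM (1.25, SE 0.218, adjusted p = 0.0178), and F2rl1, a protease-activated receptor, from 24.7 to 45.2 CPM (0.87, SE 0.169, adjusted p = 0.0201). Hs3st3b1, a heparan sulfate enzyme, rose from 12.6 to 22.7 CPM (0.85, SE 0.174, adjusted p = 0.0248). Actn1, which crosslinks actin (chromosome 12, 80167547 to 80260371), rose from 105 ± 2.87 to 181 ± 4.52 CPM (0.79, SE 0.114, adjusted p = 0.00674). The transcription factor gene Runx1 (chromosome 16, 92601466 to 92826149) rose from 49.1 ± 4.25 to 80.5 ± 2.14 CPM (0.71, SE 0.117, adjusted p = 0.0104), the integrin gene Itga6 from 52.4 to 84.9 CPM (0.70, SE 0.132, adjusted p = 0.0178), and the acetate enzyme gene Acss1 from 42.8 to 69.2 CPM (0.69, SE 0.145, adjusted p = 0.0282).

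The largest fall was in Ifi204, an interferon-induced gene with close copies (chromosome 1, 173747293 to 173766943), from 102 ± 26.0 to 34.1 ± 4.85 CPM (-1.57, SE 0.177, adjusted p = 0.00386). Ksr1, a scaffold of the MAP kinase pathway, fell from 34.7 to 13.7 CPM (-1.33, SE 0.211, adjusted p = 0.00990), and Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), from 21.0 ± 0.133 to 9.19 ± 1.73 CPM (-1.18, SE 0.169, adjusted p = 0.00571). The kinetochore gene Cenpk fell from 14.97 to 6.53 CPM (-1.19, SE 0.277, adjusted p = 0.0479) and the cell cycle factor gene Mybl2 from 32.3 to 14.3 CPM (-1.17, SE 0.218, adjusted p = 0.0201). Il18rap, an interleukin 18 receptor chain, went from 46.7 to 20.9 CPM (-1.16, SE 0.205, adjusted p = 0.0270).

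The mitosis and DNA replication lists held the most genes past the threshold in Tfh cells. Of 60 mitosis genes, 30 fell and 0 rose (51 fell and 2 rose adjusted over the list alone), with a median log2 fold change of -0.61 (adjusted p = 5.52e-47 by camera, and adjusted p = 0.196 with an estimated correlation). Among them Ccna2, a cyclin, fell from 155 to 89.6 CPM (-0.79, adjusted p = 0.00386), Birc5 from 101 to 57.6 CPM (-0.81, adjusted p = 0.00674) and Bub1b, a spindle checkpoint kinase, from 102 to 61.3 CPM (-0.73, adjusted p = 0.00990). Of 44 DNA replication genes, 20 fell and 0 rose (36 fell adjusted over the list alone). The median was -0.56 (adjusted p = 8.72e-43, and adjusted p = 0.187 with an estimated correlation). Mcm5, a subunit of the replicative helicase, fell from 241 to 144 CPM (-0.74, adjusted p = 0.00183) and Uhrf1, which maintains DNA methylation, from 77.5 to 46.5 CPM (-0.73, adjusted p = 0.00571). The histone list had a median of -0.43, with 1 of 14 genes past the threshold, H2afz, which fell from 229 to 167 CPM (-0.46, adjusted p = 0.0201), and 5 adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.199 with an estimated correlation). Among 17 cell cycle inhibitors the antiproliferative genes Btg1, from 542 to 762 CPM (0.49, adjusted p = 0.00919), and Btg2, from 268 to 342 CPM (0.35, adjusted p = 0.0435), rose while Cdkn1a fell (median 0.14, camera adjusted p = 0.0444, and adjusted p = 0.405 with an estimated correlation). Adjusted over that list alone, 5 rose and 2 fell.

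In the naive and memory list 7 of 31 genes rose and 0 fell in Tfh cells (15 rose adjusted over the list alone). The median was 0.42 (camera adjusted p = 1.24e-13, and adjusted p = 0.187 with an estimated correlation). Besides Actn1 and Lef1, they included the forkhead factor genes Foxp1, from 133 to 199 CPM (0.59, adjusted p = 0.00571), and Foxo1, from 214 to 286 CPM (0.42, adjusted p = 0.0178). The Th1 and effector list had 2 of 40 genes that fell (5 adjusted over the list alone). The median was -0.35 (camera adjusted p = 0.000251, and adjusted p = 0.514 with an estimated correlation). These were S100a4, a calcium-binding protein of memory and effector cells, from 79.8 to 38.8 CPM (-1.04, adjusted p = 0.000735), and Il18rap. Of 26 reported Bach2-repressed genes, 1 fell and 1 rose: the costimulatory receptor gene Tnfrsf9 went from 86.1 to 56.6 CPM (-0.60, adjusted p = 0.0302), and the Th2 factor gene Gata3 from 80.4 to 110 CPM (0.45, adjusted p = 0.0465). Adjusted over that list alone, 10 fell and 1 rose, and its median was -0.48, or -0.43 with genes at the counting floor set to their bound (camera adjusted p = 5.17e-05, and adjusted p = 0.187 with an estimated correlation).

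Of 37 Tfh programme genes 1 fell, Tigit. The median was -0.16 (camera adjusted p = 0.0392, and adjusted p = 0.766 with an estimated correlation). Adjusted over that list alone, 2 rose and 3 fell. In the core panel of 26 helper T cell genes, 1 rose, Lef1, and 0 fell; adjusted over the panel alone, 6 rose (Selplg, Ccr7, S1pr1, Id3, Tcf7, Lef1) and 6 fell (Bcl6, Il21, Cd40lg, Ifng, Gzmb, Il2ra). Over all genes, changes not past the threshold included the Tfh cytokine gene Il21 (346 to 220 CPM, -0.65, adjusted p = 0.208), the homing receptor gene Ccr7 (0.80, adjusted p = 0.141), Ifng (-0.84, adjusted p = 0.106), Prdm1 (-0.14, adjusted p = 0.896), Tcf7 (0.25, adjusted p = 0.188) and Tbx21 (-0.01, adjusted p = 0.989). Costimulatory and inhibitory receptors had 1 rise (Cd96, 0.40, adjusted p = 0.0343) and 2 falls (Tigit, Tnfrsf9) in 31 genes, or 2 and 8 adjusted over the list alone. The median was -0.13 (camera adjusted p = 0.0392, and adjusted p = 0.308 with an estimated correlation).

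Metabolic lists had small negative medians in Tfh cells, and few of their genes passed. All 24 cholesterol synthesis genes had a negative estimate (median -0.32), and 2 fell, among them the isoprenoid enzyme gene Idi1, from 31.7 to 17.7 CPM (-0.84, adjusted p = 0.00963), against 12 adjusted over the list alone (camera adjusted p = 1.14e-08, and adjusted p = 0.187 with an estimated correlation). In glycolysis 3 of 26 genes fell (8 adjusted over the list alone), among them Pgk1 from 174 to 119 CPM (-0.55, adjusted p = 0.00882) and Gapdh from 996 to 752 CPM (-0.41, adjusted p = 0.0245). The median was -0.23 (camera adjusted p = 1.12e-05, and adjusted p = 0.196 with an estimated correlation). All 49 oxidative phosphorylation genes had a negative estimate (median -0.17), and 1 fell, the cytochrome gene Cycs, from 83.3 to 60.04 CPM (-0.47, adjusted p = 0.0483), or 4 adjusted over the list alone (camera adjusted p = 8.93e-09, and adjusted p = 0.405 with an estimated correlation). Amino acid transport and mTORC1 genes had a median of -0.13, with 2 of 20 that fell, among them the serine synthesis gene Phgdh, from 151 to 109 CPM (-0.47, adjusted p = 0.0245), and 3 that fell and 1 that rose adjusted over the list alone (camera adjusted p = 0.0444, and adjusted p = 0.234 with an estimated correlation). The interferon list had 3 of 47 genes that fell, Ifi204, Oasl2 from 37.1 to 18.0 CPM (-1.03, adjusted p = 0.0110) and Ly6a from 1230 to 917 CPM (-0.42, adjusted p = 0.0178), or 12 and 1 rise adjusted over the list alone. The median was -0.18 (camera adjusted p = 5.88e-06, and adjusted p = 0.405 with an estimated correlation).

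Among other lists in Tfh cells, the heme and oxidative stress list had a median of -0.21, with 1 of 22 genes that fell, the peroxidase gene Prdx1, from 647 to 480 CPM (-0.43, adjusted p = 0.0195), or 5 adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.187 with an estimated correlation). The p53 response had a median of -0.14, or -0.11 with floor genes at their bound, with 2 of 30 that fell (Cdkn1a, Ckap2) and 1 that rose (Btg2), and 3 and 1 adjusted over the list alone (camera adjusted p = 0.0267, and adjusted p = 0.199 with an estimated correlation). In the Th17 list (11 genes) the median was -0.88, with 0 past the threshold (camera adjusted p = 0.00204, and adjusted p = 0.481 with an estimated correlation). Th2 genes had a median of -0.78 over 8 genes while their 1 call, Gata3, was a rise (camera adjusted p = 0.0428, and adjusted p = 0.405 with an estimated correlation), and adjusted over the list alone 1 rose and 2 fell. Treg and Tfr genes had a median of -0.18 with 1 of 16 that fell, Tnfrsf9, or 3 adjusted over the list alone (camera adjusted p = 0.0397, and adjusted p = 0.234 with an estimated correlation). The 14 mitochondrially encoded genes had a median of 0.14 with 0 past the threshold (camera adjusted p = 0.0177, and adjusted p = 0.726 with an estimated correlation).

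In this comparison 20 of 37 lists were past the threshold with camera's preset correlation, 3 upward and 17 downward, 0 with an estimated correlation and 8 with fry. The gene count depended on single libraries: 15 genes passed without replicate 2 of the Tfh cells with empty vector and 36 without replicate 2 of those with Bach2. Of the 15 genes that the naming rule chose by size of change, Ifi204, Cdc6 and Cdkn1a passed whichever library was left out, while 12 were lost without replicate 2 and 6 without replicate 1 of the Tfh cells with empty vector, and 10 and 2 without replicates 2 and 1 of those with Bach2. Tigit passed in 18 of 19 alternatives (adjusted p up to 0.512, against a 1.5-fold change). Of the 20 lists, 6 were lost without either empty vector Tfh library or without replicate 1 of the Bach2 Tfh cells and 3 without replicate 2, but never mitosis, DNA replication or the naive and memory list. Against a 1.5-fold change, 1 gene passed, Bach2. DESeq2 called 313 genes. Without replicate 1 of the Bach2 Tfh cells, 125 genes rose and 111 fell.

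In non-Tfh cells with the Bach2 vector, 5 of 31 costimulatory and inhibitory receptors, 7 of 40 Th1 and effector genes and 4 of 11 Th17 genes fell. As lists these were past the threshold at the preset correlation, with adjusted p = 0.0636, 0.225 and 0.119 with an estimated correlation. Tigit (chromosome 16, 43648867 to 43664146) fell from 64.0 ± 12.3 to 13.2 ± 0.485 CPM (SD, n = 2), with a log2 fold change of -2.27 (SE 0.146, adjusted p = 4.17e-06). Gpr15, a homing receptor for the gut (chromosome 16, 58717433 to 58719070), fell from 82.4 ± 1.32 to 29.0 ± 5.43 CPM (-1.51, SE 0.162, adjusted p = 0.000479). Havcr2, which encodes the inhibitory receptor TIM-3 (chromosome 11, 46454935 to 46481255), fell from 48.7 ± 3.18 to 15.3 ± 3.31 CPM (-1.66, SE 0.230, adjusted p = 0.00467). Prdm1, which encodes the effector factor Blimp-1, fell from 28.5 to 12.3 CPM (-1.21, SE 0.227, adjusted p = 0.0212) and Ifng from 81.7 to 33.9 CPM (-1.27, SE 0.198, adjusted p = 0.0128). In all, 29 genes rose and 71 fell among 11475, and 30 changed at least 2-fold.

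Other large falls in non-Tfh cells were Ccl4, a chemokine gene with close copies, from 14.3 to 3.15 CPM (-2.17, SE 0.378, adjusted p = 0.0153), the matrix gene Matn2 from 20.1 to 5.13 CPM (-1.96, SE 0.334, adjusted p = 0.0153) and the plexin-domain gene Plxdc1 from 15.7 to 4.85 CPM (-1.69, SE 0.263, adjusted p = 0.00774). Ifi204 fell from 147 ± 19.7 to 45.9 ± 1.27 CPM (-1.68, SE 0.171, adjusted p = 0.00158) and the magnesium channel gene Trpm6 to 5.16 CPM (-1.52, SE 0.265, adjusted p = 0.0162). The largest rises were Tent5a, an RNA-tailing enzyme gene, from 19.5 to 43.6 CPM (1.16, SE 0.240, adjusted p = 0.0472), Scml4 from 66.0 ± 1.56 to 124.5 ± 11.4 CPM (0.92, SE 0.171, adjusted p = 0.0298), the testis-development gene Tdrp from 29.2 to 51.6 CPM (0.82, SE 0.171, adjusted p = 0.0389) and Pik3ip1, an inhibitor of PI3 kinase, from 50.2 to 84.7 CPM (0.76, SE 0.127, adjusted p = 0.0128). Xdh, a purine-degrading enzyme gene (chromosome 17, 73883895 to 73950196), rose from 107 ± 1.21 to 177 ± 23.1 CPM (0.73, SE 0.101, adjusted p = 0.00413), the TGF-beta inhibitor gene Smad7 from 38.4 to 63.8 CPM (0.73, SE 0.158, adjusted p = 0.0472) and the lectin receptor gene Klrd1 from 33.5 to 55.4 CPM (0.72, SE 0.154, adjusted p = 0.0436).

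Of 26 reported Bach2-repressed genes, 6 fell in non-Tfh cells and 0 rose (13 and 1 adjusted over the list alone), with a median of -0.76. Camera gave an adjusted p of 5.90e-21. With an estimated correlation, not tried with a library left out, the list stayed past the threshold (adjusted p = 0.0328). Besides Havcr2, Ifng and Prdm1 these were Ahr, a receptor factor of Th17 cells, from 73.4 to 29.1 CPM (-1.33, adjusted p = 0.000479), Tnfrsf9 from 63.9 to 32.9 CPM (-0.96, adjusted p = 0.00416) and Rora from 84.8 to 39.4 CPM (-1.11, adjusted p = 0.0436). After the members shared with the Th1 list were taken out, a choice made after seeing the data, 3 of 17 fell. Their median was -0.88 (adjusted p = 0.0602 with an estimated correlation). Without those shared with the Th17 list, 4 of 24 fell. The median was -0.62 (adjusted p = 0.0636 with an estimated correlation).

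Among 11 Th17 genes, 4 fell and 0 rose in non-Tfh cells (6 fell adjusted over the list alone). The median was -1.33 (camera adjusted p = 6.14e-21, and adjusted p = 0.119 with an estimated correlation). The cytokine gene Il17f went from 6.27 to 0.527 CPM (-3.53, adjusted p = 0.0135) and the receptor gene Il17re from 9.75 to 2.49 CPM (-1.96, adjusted p = 0.0128). In the Th1 and effector list 7 of 40 fell and 1 rose, Klrd1 (19 and 3 adjusted over the list alone). The median was -0.37 (camera adjusted p = 8.70e-15, and adjusted p = 0.225 with an estimated correlation). S100a4 fell from 294 to 140 CPM (-1.07, adjusted p = 8.94e-05). Costimulatory and inhibitory receptors had 5 falls in 31 genes (8, with 1 rise, adjusted over the list alone), among them Lag3 from 48.3 to 30.1 CPM (-0.68, adjusted p = 0.0281). The median was -0.20 (camera adjusted p = 2.12e-11, and adjusted p = 0.0636 with an estimated correlation). The interferon list had 5 falls in 47 genes (10 adjusted over the list alone), among them Oas3 from 234 to 150 CPM (-0.64, adjusted p = 0.0135). The median was -0.20 (camera adjusted p = 2.95e-11, and adjusted p = 0.272 with an estimated correlation).

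In the naive and memory list 3 of 31 rose in non-Tfh cells (13 adjusted over the list alone): Lef1 from 170 to 256 CPM (0.59, adjusted p = 0.00748), Rflnb from 77.9 to 121 CPM (0.64, adjusted p = 0.0293) and the survival gene Bcl2 from 40.4 to 65.1 CPM (0.69, adjusted p = 0.0311). The median was 0.23 (camera adjusted p = 7.93e-13, and adjusted p = 0.147 with an estimated correlation). Of 37 Tfh programme genes 2 fell, Tigit and Maf, the latter from 133 to 93.1 CPM (-0.52, adjusted p = 0.0431), or 7 adjusted over the list alone. The median was -0.20 (camera adjusted p = 1.35e-10, and adjusted p = 0.310 with an estimated correlation). In the core panel 1 rose and 3 fell over all genes; adjusted over the panel alone 4 rose (Ccr7, Id3, Tcf7, Lef1) and 10 fell (Bcl6, Icos, Il21, Cd40lg, Tox2, Maf, Prdm1, Ifng, Gzmb, Il2ra). Over all genes, changes not past the threshold included Icos (927 to 667 CPM, -0.47, adjusted p = 0.0515), Gzmb (-1.46, adjusted p = 0.0608), Il21 (59.2 to 22.7 CPM, -1.39, adjusted p = 0.0862) and Bcl6 (-0.56, adjusted p = 0.145).

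Of 75 cytosolic ribosomal protein genes, 74 had a positive estimate in non-Tfh cells, with a median of 0.16, 0 past the threshold and 14 rises adjusted over the list alone (camera adjusted p = 8.70e-15, and adjusted p = 0.394 with an estimated correlation). Mitosis (median -0.16, camera adjusted p = 3.36e-05, and adjusted p = 0.616 with an estimated correlation) and DNA replication (median -0.14, camera adjusted p = 0.000272, and adjusted p = 0.541 with an estimated correlation) held 0 genes past the threshold, with Mcm5 at 300 and 260 CPM (-0.21, adjusted p = 0.411). The unfolded protein response had 1 fall in 24 genes, the stress factor gene Atf6, from 79.6 to 49.0 CPM (-0.70, adjusted p = 0.00705), or 9 adjusted over the list alone. The median was -0.21 (camera adjusted p = 4.52e-06, and adjusted p = 0.0997 with an estimated correlation). In the heme and oxidative stress list Prdx1 fell from 634 to 444 CPM (-0.51, adjusted p = 0.00949), 3 of 22 fell adjusted over the list alone, and the median was -0.17 (camera adjusted p = 4.65e-05, and adjusted p = 0.0997 with an estimated correlation). The p53 response had 2 falls in 30, with or without adjustment over the list alone, Plk3 (-0.64, adjusted p = 0.00782) and Cdkn1a from 46.7 to 20.9 CPM (-1.16, adjusted p = 0.00193). The median was -0.11 (camera adjusted p = 0.0113, and adjusted p = 0.161 with an estimated correlation). The early TCR response had 2 falls in 30, Tnfrsf9 and Irf8 (-0.54, adjusted p = 0.0435), 4 and 1 rise adjusted over the list alone. The median was -0.07 (camera adjusted p = 0.0348, and adjusted p = 0.602 with an estimated correlation).

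The cholesterol list held 0 genes past the threshold in non-Tfh cells and 3 falls adjusted over the list alone. The median was -0.22 (camera adjusted p = 9.23e-06, and adjusted p = 0.147 with an estimated correlation). Glycolysis also held 0, with 2 falls and 1 rise adjusted over the list alone. The median was -0.17 (camera adjusted p = 0.0162, and adjusted p = 0.394 with an estimated correlation). In oxidative phosphorylation 0 genes passed, and the median was -0.10 (camera adjusted p = 0.000731, and adjusted p = 0.616 with an estimated correlation). The 5 CD8 T cell markers had a median of 0.39 with 0 past the threshold and 2 rises adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.454 with an estimated correlation); Klrk1 was at 47.1 and 97.1 CPM (1.04, adjusted p = 0.186).

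In non-Tfh cells 18 of 37 lists were past the threshold with the preset correlation, 3 upward and 15 downward, 1 with an estimated correlation and 4 with fry. The gene count was 14 without replicate 2 and 28 without replicate 1 of the non-Tfh cells with empty vector, and 41 without replicate 2 and 66 without replicate 1 of those with Bach2; in the last case 38 rose and 28 fell. Of the 15 genes chosen by size of change, Tigit, Ifi204 and Gpr15 passed whichever library was left out, while 12 and 8 were lost without replicates 2 and 1 of the empty vector non-Tfh cells and 7 and 6 without those of the Bach2 non-Tfh cells. Of the 18 lists 4 were lost without replicate 2 of the Bach2 non-Tfh cells, DNA replication among them. Against a 1.5-fold change, 8 genes passed.

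**Figure D2:**
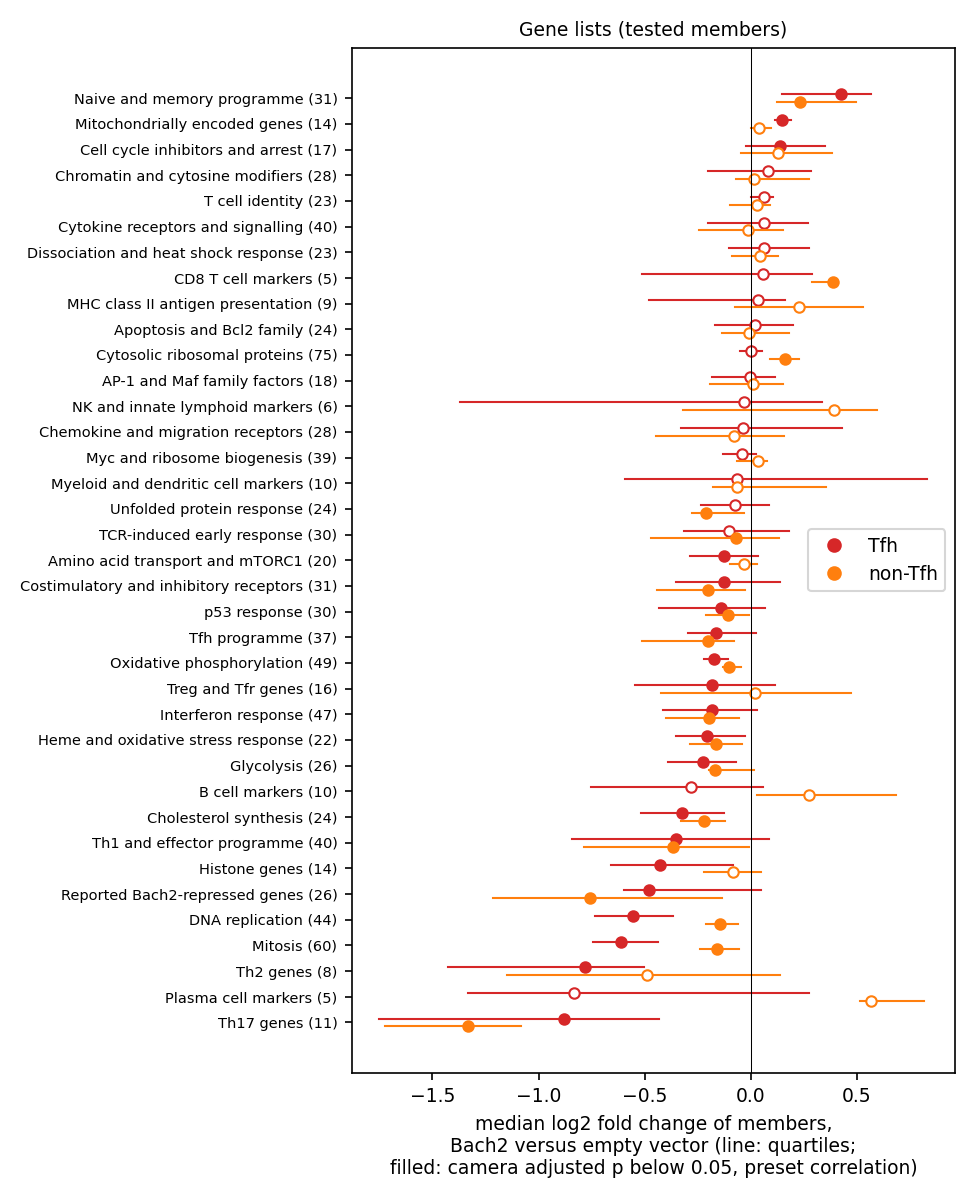
Median log2 fold change (x axis) of the tested members of 37 gene lists (y axis) for Bach2 against empty vector in Tfh cells (red) and non-Tfh cells (orange). Lines span the quartiles over genes, and filled points have a camera adjusted p below 0.05 at the preset correlation (20 and 18 lists).

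Genes that the vector changed in either cell type mostly moved in the same direction in the other. Rises in both numbered 11 besides Bach2, of 62 in Tfh and 28 in non-Tfh cells (0.151 expected if unrelated). Among them were Lef1, Scml4, Btg1 and Xdh. Falls in both numbered 16, of 133 and 71 (0.823 expected), among them Tigit, S100a4, Ifi204, Cdkn1a, Tnfrsf9 and Prdx1. In opposite directions 0 genes changed. Over 11474 genes without Bach2, the log2 fold changes had a Pearson correlation of 0.307 and a Spearman correlation of 0.378, and over the 267 genes called in either cell type 0.613, with 253 of these (94.8%) alike in sign. Genes are not independent replicates, so these overlaps and correlations carry no p-value. The pair of comparisons shares no library but shares 1 fit. With the stricter CPM filter the Pearson correlation was 0.531, and with no filter 0.0281.

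**Figure D3:**
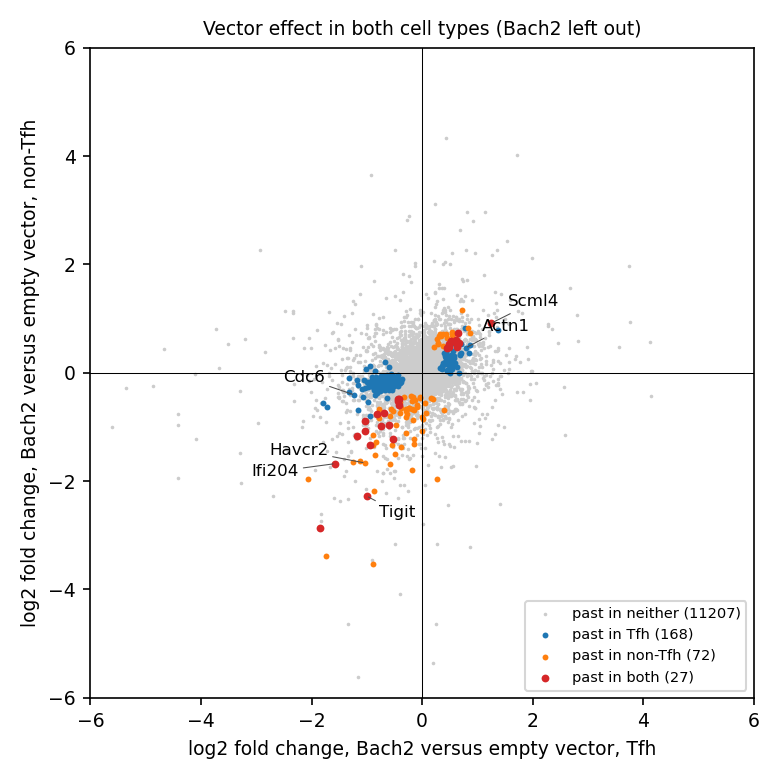
Log2 fold change of Bach2 against empty vector in Tfh cells (x axis) and in non-Tfh cells (y axis) for 11474 genes without Bach2. Points are genes, colored by adjusted p below 0.05 in neither (11207), Tfh only (168), non-Tfh only (72) or both (27).

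In the fit without a replicate block, no gene passed a test of whether the vector effect differed between the cell types. The smallest unadjusted p was that of Tigit (difference 1.27, SE 0.187, adjusted p = 0.131 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment; the range over alternatives was 2.73e-12 to 1). B4galnt4, a glycosylation enzyme gene, went from 33.1 to 13.3 CPM in non-Tfh and from 79.8 to 72.3 CPM in Tfh cells (1.17, SE 0.188, adjusted p = 0.131). Lag3 was at 80.9 and 107 CPM in Tfh and fell from 48.3 to 30.1 CPM in non-Tfh cells (1.08, SE 0.182, adjusted p = 0.141), and the receptor gene Tnfrsf26 was at 139.9 and 140.7 CPM in Tfh and at 95.2 and 54.1 CPM in non-Tfh cells (0.82, SE 0.142, adjusted p = 0.141). In the other direction were Uhrf1 (-0.68, SE 0.144, adjusted p = 0.408), the coactivator gene Ncoa7 (-0.75, SE 0.160, adjusted p = 0.408), Mcm5 (-0.53, SE 0.122, adjusted p = 0.547) and Ccna2 (-0.63, SE 0.147, adjusted p = 0.547).

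The interaction of Bach2 itself was 0.93 (SE 0.200, adjusted p = 0.408; range over alternatives 0.00128 to 1). Genes past the threshold in 1 cell type only are thus not shown to differ in this fit: the interaction was 1.02 for Gpr15 (adjusted p = 0.657), 0.79 for Ahr (adjusted p = 0.657), 0.63 for Havcr2 (adjusted p = 0.998), 1.07 for Prdm1 (adjusted p = 0.985), 0.33 for Actn1 (adjusted p = 0.998) and -0.43 for Bub1b (adjusted p = 0.932). Of 11475 genes, 539 had an unadjusted p below 0.05 against 573.75 expected by chance, and the median SE of an interaction was 0.221 on the log2 scale. DESeq2 called 5 genes and limma-voom 0. With edgeR, 37 genes passed with no filter, 3 with the replicate number as a block and 70 with a block within each vector. The labels do not pair the replicate numbers, and the count of 0 depends on the settings. Of the 37 lists 12 were past the threshold with the preset correlation, 5 upward and 7 downward, 0 with an estimated correlation (smallest adjusted p 0.424) and 0 with fry.

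With empty vector, Tfh cells differed from non-Tfh cells in transcription factors, cytokines and receptors of helper lineages. Bcl6 rose from 22.4 CPM in non-Tfh to 147 CPM in Tfh cells (2.72, SE 0.138, adjusted p = 2.29e-08), Tox2, a factor that promotes Tfh fate, from 24.1 to 418 CPM (4.12, SE 0.265, adjusted p = 5.78e-05) and Il21 from 59.2 to 346 CPM (2.55, SE 0.234, adjusted p = 0.000290). Prdm1 fell from 28.5 to 2.66 CPM (-3.43, SE 0.277, adjusted p = 1.05e-06) and Il2ra, the high-affinity interleukin 2 receptor chain (chromosome 2, 11642807 to 11693193), from 127 ± 5.23 to 8.06 ± 1.37 CPM (SD, n = 2; -3.96, SE 0.166, adjusted p = 8.13e-09). In all, 1213 genes rose and 1302 fell among 11475, and 899 changed at least 2-fold.

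The largest rise in Tfh cells was Padi4, a protein-citrullinating enzyme gene, with 1 count in non-Tfh and 222 in Tfh cells, a ratio of 226 (counting interval 40.1 to 8947). Sostdc1, a secreted inhibitor of BMP and Wnt signals, rose from 1.21 to 149 ± 69.1 CPM (6.93, SE 0.845, adjusted p = 0.00632), and H2-Q2, an MHC class I gene with close copies (chromosome 17, 35342242 to 35346762), from 1.82 ± 0.260 to 202 ± 51.1 CPM (6.79, SE 0.260, adjusted p = 7.04e-08). The transcription factor gene Cebpa went from 0.932 to 52.7 ± 13.4 CPM (5.80, SE 0.448, adjusted p = 1.85e-05), and Fam43a from 0.716 to 40.1 CPM (5.79, SE 0.449, adjusted p = 1.20e-05). The cytokine gene Il4 had 3 and 1 counts in the non-Tfh libraries and 12.1 ± 2.84 CPM in Tfh cells (5.70, SE 0.622, adjusted p = 2.25e-05). The gate gene Cxcr5 was higher by 5.05, which the sorting sets.

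The largest falls in Tfh cells were Itga2, a collagen receptor gene, from 15.3 to 0.390 CPM (-5.24, SE 0.468, adjusted p = 2.99e-06), the chemokine receptor gene Ccr2 from 257 to 13.6 CPM (-4.26, SE 0.532, adjusted p = 0.00669) and the integrin gene Itgb3 from 66.5 to 3.93 CPM (-4.11, SE 0.690, adjusted p = 0.0140). Ust, a sulfotransferase gene (-4.01, SE 0.365, adjusted p = 3.20e-06), Adam8, a membrane protease gene (-3.90, SE 0.341, adjusted p = 3.27e-06), Ly6c2, a gene with a close copy, from 187 to 13.3 CPM (-3.85, SE 0.364, adjusted p = 0.000888), and the histamine receptor gene Hrh4 from 71.2 to 5.03 CPM (-3.82, SE 0.174, adjusted p = 9.89e-09) followed. In the core panel 12 rose and 10 fell (13 and 12 adjusted over the panel alone). Rises included Tcf7 (1.12, adjusted p = 1.19e-06), Lef1 (0.89, adjusted p = 9.38e-06) and Ascl2 (ratio 91.4, counting interval 16.0 to 3651), and falls Tbx21 (-1.94, adjusted p = 0.000227), Ifng (-2.12, adjusted p = 1.96e-05), Gzmb (-3.82, adjusted p = 6.38e-05) and Selplg from 1352 to 495 CPM (-1.45, adjusted p = 5.43e-07). Not past the threshold were Cd40lg (0.29, adjusted p = 0.0767), Batf (0.09, adjusted p = 0.524), S1pr1 (-0.41, adjusted p = 0.122) and Klf2 (-0.95, adjusted p = 0.0787).

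Of 37 Tfh programme genes 32 rose and 3 fell in Tfh cells with empty vector (33 and 3 adjusted over the list alone). The median was 1.20 (camera adjusted p = 2.92e-41, and adjusted p = 0.108 with an estimated correlation). Tigit rose by 2.56 (adjusted p = 2.45e-08) and the ATP receptor gene P2rx7 from 64.3 to 434 CPM (2.76, adjusted p = 8.13e-09). In the Th1 and effector list 34 of 40 fell and 1 rose, Stat4 (37 and 1 adjusted over the list alone). The median was -2.64 (camera adjusted p = 4.86e-53, and adjusted p = 0.108 with an estimated correlation). Klrd1 fell (-3.27, adjusted p = 9.09e-08) and the chemokine receptor gene Cxcr6 went from 674 to 68.0 CPM (-3.31, adjusted p = 2.40e-06). Of 26 reported Bach2-repressed genes 19 fell and 4 rose (21 and 4 adjusted over the list alone). The median was -2.03 (camera adjusted p = 2.81e-25), and the list stayed past the threshold with an estimated correlation (adjusted p = 0.0241). Bhlhe40, an effector cytokine factor and member of that list, fell from 302 to 57.0 CPM (-2.41, adjusted p = 4.16e-08). Without its Th1 members the list's value with an estimated correlation was 0.108, and without its Th17 members 0.0495. Among 11 Th17 genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), such as Ahr (-1.93, adjusted p = 8.40e-07). The median was -2.26 (camera adjusted p = 6.34e-06, and adjusted p = 0.432 with an estimated correlation).

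All genes past the threshold in the lists of growth (Myc) and protein folding were lower in Tfh than in non-Tfh cells with empty vector. Of 39 Myc and ribosome biogenesis genes 24 fell and 0 rose (28 adjusted over the list alone). The median was -0.44 (camera adjusted p = 4.23e-09, and adjusted p = 0.108 with an estimated correlation). Myc itself went from 73.0 to 24.8 CPM (-1.56, adjusted p = 3.38e-05). In the unfolded protein response 12 of 24 fell with either adjustment, such as the chaperone gene Hsp90b1 from 731 to 322 CPM (-1.18, adjusted p = 2.46e-06). The median was -0.34 (camera adjusted p = 0.00138, and adjusted p = 0.178 with an estimated correlation). The interferon list had 14 falls in 47 with either adjustment, such as Gbp7 from 229 to 75.9 CPM (-1.59, adjusted p = 4.07e-07). The median was -0.24 (camera adjusted p = 0.00506, and adjusted p = 0.670 with an estimated correlation). DNA replication had 7 falls and 1 rise, Mcm6 (0.43, adjusted p = 0.00346), in 44 genes with either adjustment. The median was -0.16 (camera adjusted p = 0.0473, and adjusted p = 0.769 with an estimated correlation).

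Chemokine and migration receptors had 15 falls and 5 rises in 28 genes (17 and 5 adjusted over the list alone). The median was -1.16 (camera adjusted p = 4.55e-06, and adjusted p = 0.200 with an estimated correlation). Cytokine receptors and signalling had 13 falls and 10 rises in 40 (14 and 11 adjusted over the list alone). The median was -0.08 (camera adjusted p = 0.00810, and adjusted p = 0.670 with an estimated correlation). For Treg and Tfr genes there were 8 falls and 4 rises in 16 (10 and 4 adjusted over the list alone), among the rises Ikzf2 from 11.5 to 86.1 CPM (2.90, adjusted p = 5.53e-08), and the median was -0.62 (camera adjusted p = 0.00250, and adjusted p = 0.157 with an estimated correlation). T cell identity genes had 11 rises and 3 falls in 23 with either adjustment, such as Cd247, a signalling chain of the T cell receptor (0.52, adjusted p = 0.000289). The median was 0.30 (camera adjusted p = 0.0314, and adjusted p = 0.670 with an estimated correlation). Of 5 CD8 T cell markers 3 fell with either adjustment, the receptor genes Klrc1 (-2.88, adjusted p = 5.61e-08), Klrk1 and Klrc2. The median was -2.88 (camera adjusted p = 0.000371, and adjusted p = 0.265 with an estimated correlation).

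Of the lists, 13 were past the threshold with the preset correlation, 2 upward and 11 downward, 1 with an estimated correlation and 18 with fry. Against a 1.5-fold change 702 genes passed. The gene count was 1340 without replicate 2 and 1656 without replicate 1 of the non-Tfh cells with empty vector, and 1401 without replicate 1 of the Tfh cells. Sostdc1 was lost without either non-Tfh library, Itgb3 without replicate 2 of the non-Tfh cells or either Tfh library, and Ccr2 without replicate 1 of the Tfh cells. The DNA replication call ended in 4 of the 8 cases with a library left out.

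With the Bach2 vector, Tfh and non-Tfh cells differed in many of the same genes, and 32 of 44 DNA replication genes were lower in Tfh cells (adjusted p = 0.261 for the list with an estimated correlation). Bcl6 was higher by 2.87 (adjusted p = 2.10e-08), Il21 by 3.28 (adjusted p = 0.000115), Tigit by 3.83 (adjusted p = 4.26e-09) and Tox2 by 4.87, from 12.1 to 353 CPM (SE 0.286, adjusted p = 3.63e-05). Mcm5 fell from 260 CPM in non-Tfh to 144 CPM in Tfh cells (-0.85, adjusted p = 8.67e-06), Uhrf1 from 106 to 46.5 CPM (-1.18, adjusted p = 2.43e-06) and Ccna2 from 172 to 89.6 CPM (-0.94, adjusted p = 1.88e-05). Il2ra fell from 94.5 ± 11.7 to 5.54 ± 1.39 CPM (SD, n = 2; -4.10, SE 0.176, adjusted p = 5.59e-09). In all, 1335 genes rose and 1461 fell among 11475, and 957 changed at least 2-fold.

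The largest rises were Cebpa from 0.260 to 34.2 CPM (6.94, SE 0.560, adjusted p = 2.37e-05), Fam43a from 0.363 to 42.1 CPM (6.78, SE 0.494, adjusted p = 7.25e-06), Sostdc1 from 1.61 to 152 ± 71.3 CPM (6.57, SE 0.806, adjusted p = 0.00568) and H2-Q2 from 2.74 to 249 ± 35.2 CPM (6.49, SE 0.243, adjusted p = 7.46e-08). Padi4 followed, from 0.260 to 15.8 CPM (5.83, SE 0.533, adjusted p = 4.32e-06), and the gate gene Cxcr5 was higher by 4.91. Among the largest falls, Ust (-4.49, SE 0.387, adjusted p = 2.16e-06), Ccr2 (-4.16, SE 0.551, adjusted p = 0.00720), Ly6c2 (-3.94, SE 0.354, adjusted p = 0.000658) and Hrh4 (-3.94, SE 0.191, adjusted p = 1.60e-08) were also among those with empty vector. The others were Igfbp4, an IGF-binding protein gene, from 40.7 to 1.95 CPM (-4.38, SE 0.366, adjusted p = 8.04e-06), the activating receptor gene Klrk1 from 97.1 to 6.35 CPM (-3.95, SE 0.333, adjusted p = 6.45e-05) and AA467197 (-3.93, SE 0.425, adjusted p = 1.41e-05). In the core panel 12 rose and 9 fell (13 and 10 adjusted over the panel alone), such as Maf (0.91, adjusted p = 3.57e-05) and Prdm1 (-2.35, adjusted p = 4.98e-05). Il4 had a ratio of 77.8 (counting interval 21.1 to 648.2) and Ascl2 of 49.7 (8.48 to 2004), and Icos was not past the threshold (-0.24, adjusted p = 0.110).

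The DNA replication list had 32 falls and 1 rise, Mcm6, in 44 genes in this comparison (36 and 1 adjusted over the list alone). The median was -0.59 (camera adjusted p = 2.03e-13, and adjusted p = 0.261 with an estimated correlation). Mitosis had 34 falls and 2 rises in 60 (40 and 2 adjusted over the list alone). The median was -0.44 (camera adjusted p = 1.74e-08, and adjusted p = 0.525 with an estimated correlation). Of 75 cytosolic ribosomal protein genes 35 fell and 1 rose, Rpsa (45 and 1 adjusted over the list alone), such as Rpl29 from 186 to 108 CPM (-0.78, adjusted p = 3.31e-05). The median was -0.24 (camera adjusted p = 7.82e-07, and adjusted p = 0.564 with an estimated correlation). Of 39 Myc and ribosome biogenesis genes 31 fell with either adjustment, such as Myc (-1.97, adjusted p = 4.61e-06). The median was -0.59 (camera adjusted p = 7.56e-12, and adjusted p = 0.103 with an estimated correlation). Of 14 mitochondrially encoded genes 5 rose with either adjustment, such as mt-Nd4 (0.44, adjusted p = 0.0294). The median was 0.26 (camera adjusted p = 0.0250, and adjusted p = 0.599 with an estimated correlation).

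The Tfh programme had 31 rises and 1 fall, Irf4, in 37 genes with the Bach2 vector (32 and 2 adjusted over the list alone). The median was 1.52 (camera adjusted p = 1.07e-48, and adjusted p = 0.103 with an estimated correlation). Th1 and effector genes had 33 falls and 1 rise in 40 with either adjustment. The median was -2.21 (camera adjusted p = 1.52e-41, and adjusted p = 0.118 with an estimated correlation). Reported Bach2-repressed genes had 18 falls and 4 rises in 26 (19 and 4 adjusted over the list alone). The median was -1.41 (camera adjusted p = 4.55e-16, and adjusted p = 0.0592 with an estimated correlation). For costimulatory and inhibitory receptors there were 14 rises and 9 falls in 31 (16 and 10 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.0120, and adjusted p = 0.261 with an estimated correlation). T cell identity genes had 11 rises and 2 falls in 23 (12 and 2 adjusted over the list alone), such as Cd28 (0.72, adjusted p = 9.43e-06). The median was 0.33 (camera adjusted p = 0.00453, and adjusted p = 0.496 with an estimated correlation). Chemokine and migration receptors had 17 falls and 5 rises in 28 (18 and 5 adjusted over the list alone). The median was -1.05 (camera adjusted p = 0.000183, and adjusted p = 0.261 with an estimated correlation). Treg and Tfr genes had 10 falls and 4 rises in 16 (12 and 4 adjusted over the list alone). The median was -0.84 (camera adjusted p = 0.000676, and adjusted p = 0.118 with an estimated correlation).

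Other lists past the threshold with the Bach2 vector were the 11 Th17 genes, 6 of which fell and 1 rose with either adjustment (median -2.25, camera adjusted p = 0.0336, and adjusted p = 0.585 with an estimated correlation), as well as 24 cholesterol genes, 7 of which fell, such as Idi1 (-1.44, adjusted p = 2.90e-06), and 1 rose, or 8 and 2 adjusted over the list alone (median -0.20, camera adjusted p = 0.0228, and adjusted p = 0.353 with an estimated correlation). In the unfolded protein response 8 of 24 fell and 1 rose, Atf6, or 10 and 1 adjusted over the list alone (median -0.12, camera adjusted p = 0.0458, and adjusted p = 0.312 with an estimated correlation). In the interferon list 12 of 47 fell and 2 rose, or 14 and 2 adjusted over the list alone (median -0.18, camera adjusted p = 0.0250, and adjusted p = 0.596 with an estimated correlation), and in the p53 response 14 of 30 fell and 4 rose, or 15 and 4 adjusted over the list alone (median -0.45, camera adjusted p = 0.0458, and adjusted p = 0.261 with an estimated correlation). Cytokine receptors and signalling had 12 falls and 10 rises in 40 (12 and 11 adjusted over the list alone), with a median of 0.06 while camera, which weighs the members' statistics, called the list downward (adjusted p = 0.0442, and adjusted p = 0.596 with an estimated correlation). All 3 tested CD8 T cell markers past the threshold fell, such as Klrc1 (-3.78, adjusted p = 1.20e-08). The median was -3.78 (camera adjusted p = 7.61e-06, and adjusted p = 0.261 with an estimated correlation).

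In this comparison 19 of 37 lists were past the threshold with the preset correlation, 4 upward and 15 downward, 0 with an estimated correlation and 22 with fry. Against a 1.5-fold change 768 genes passed. Of the 16 genes chosen by size of change, 15 passed whichever library was left out, and Sostdc1 was lost without replicate 2 of the Bach2 non-Tfh cells. Of the 19 lists 5 were lost without replicate 1 of the Bach2 non-Tfh cells and 5 without replicate 2 of the Bach2 Tfh cells.

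Most genes called between cell types with either vector had the same sign with the other. Of 44 DNA replication genes, 36 (empty vector) and 42 (Bach2) had negative estimates. Rises in both numbered 919 (141 expected if unrelated), falls in both 945 (166 expected), and 0 genes changed in opposite directions. Over 11475 genes the log2 fold changes had a Pearson correlation of 0.843 and a Spearman correlation of 0.741, and over the 3447 genes called with either vector 0.903, with 3357 of these (97.4%) alike in sign. The libraries of these comparisons are separate, and genes are not independent replicates. With no filter the Pearson correlation was 0.290.

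**Figure D4:**
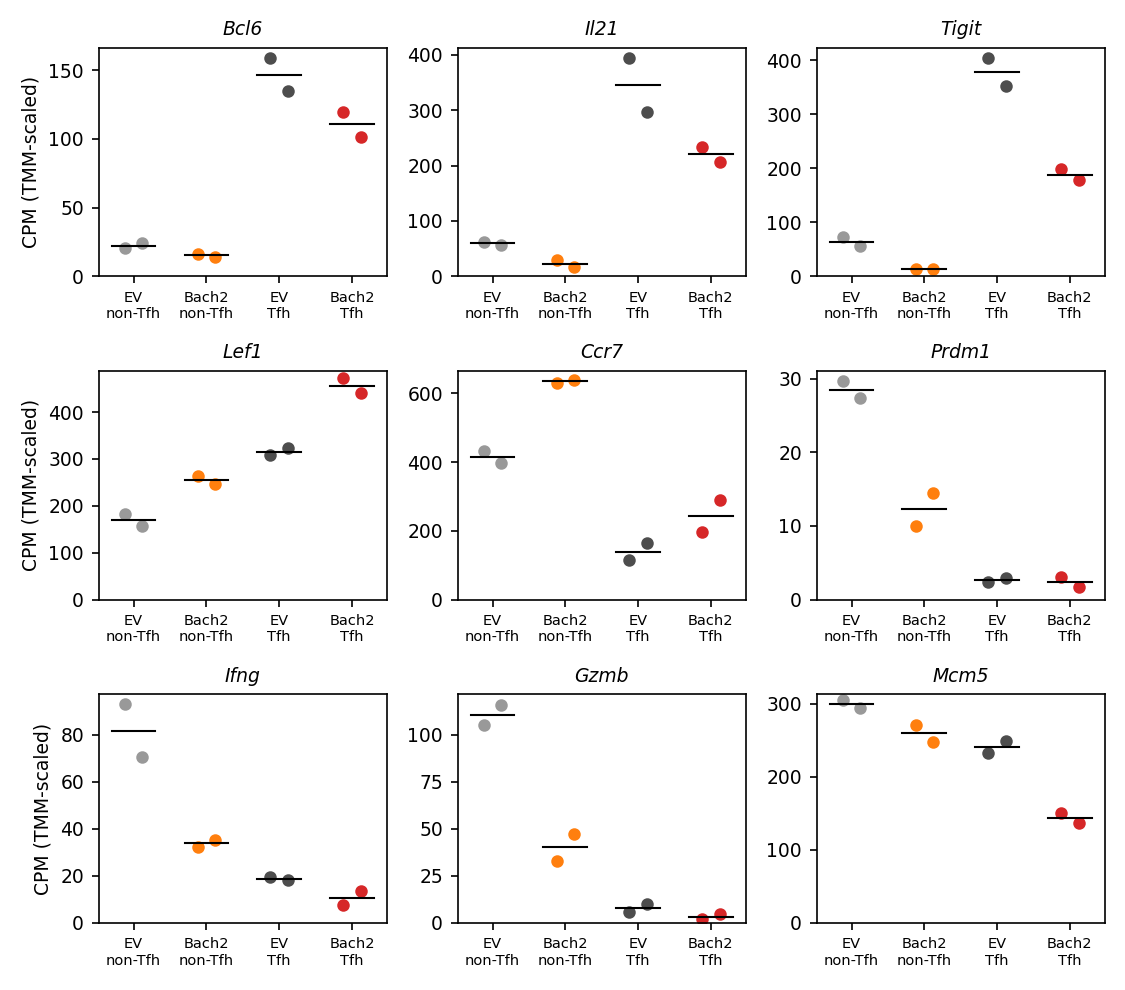
CPM per library (y axis, points) with the group mean (bar) for Bcl6, Il21, Tigit, Lef1, Ccr7, Prdm1, Ifng, Gzmb and Mcm5 in the 4 groups (x axis, n = 2). Tigit means were 64.0 and 13.2 CPM in non-Tfh cells and 377 and 188 CPM in Tfh cells (empty vector, then Bach2).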

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

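The lists and their interaction test were fixed at the start. The cell cycle check on single libraries was written before its value was seen. The estimated correlation was taken as a check afterwards. In 12 of 37 lists the effect of the Bach2 vector differed between Tfh and non-Tfh cells by camera's test of the interaction at its preset correlation. None of the 12 passed with an estimated correlation, and none of their members passed singly over all genes. Leaving out 1 library ended 2 to 6 of the 12 calls, most without replicate 2 of the Bach2 non-Tfh cells, and never those of DNA replication, mitosis or ribosomal proteins.

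The cell cycle lists had the smallest adjusted p. The median interaction was -0.448 for DNA replication (adjusted p = 4.58e-29, and adjusted p = 0.424 with an estimated correlation) and -0.411 for mitosis (adjusted p = 2.77e-29, and adjusted p = 0.424 with an estimated correlation). Adjusted over the list alone, 20 of 44 and 22 of 60 genes passed, all lower. Histone genes moved the same way (-0.328, adjusted p = 0.0104, and adjusted p = 0.424 with an estimated correlation). Over the 104 members of both cell cycle lists the median vector effect was -0.58 (SE over genes 0.0353) in Tfh cells and -0.15 (SE 0.0160) in non-Tfh cells.

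If a single library caused the difference between cell types, leaving it out would have brought the median interaction of the 104 genes above -0.2. The value closest to 0 was -0.317, without replicate 2 of the Tfh cells with empty vector, which argues against that explanation. Cells of the other gate in a library were not tested as a cause. Whether the vector acts more strongly on the cell cycle in Tfh cells stays open. The DNA replication list was not past the threshold by camera with an estimated correlation (adjusted p = 0.424). That test has 4 residual degrees of freedom, so its failure does not show that the effect is alike in both cell types.

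Lists of helper programmes and of the unfolded protein response had a positive median interaction, that is, a vector effect less negative in Tfh than in non-Tfh cells. The medians were 0.168 for the Tfh programme (adjusted p = 6.34e-05, and adjusted p = 0.514 with an estimated correlation) and 0.308 for reported Bach2-repressed genes (adjusted p = 0.00457, and adjusted p = 0.424 with an estimated correlation). For costimulatory and inhibitory receptors the median was 0.0971 (adjusted p = 0.000822, and adjusted p = 0.424 with an estimated correlation). Th17 genes had 0.579 (adjusted p = 0.0388, and adjusted p = 0.788 with an estimated correlation), and the unfolded protein response 0.0969 (adjusted p = 0.0336, and adjusted p = 0.424 with an estimated correlation). Adjusted over the list alone, Tigit passed in the Tfh list, Ahr in the Th17 list and 2 genes among costimulatory and inhibitory receptors.

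The other lists had a negative median interaction, and that of the CD8 markers was the largest in size of all 12. Cytosolic ribosomal proteins had a median of -0.167 (adjusted p = 2.16e-11, and adjusted p = 0.514 with an estimated correlation), and the 5 CD8 T cell markers -0.749 (adjusted p = 0.0336, and adjusted p = 0.514 with an estimated correlation). Glycolysis had a median of -0.100 (adjusted p = 0.0395, and adjusted p = 0.514 with an estimated correlation) and oxidative phosphorylation -0.0783 (adjusted p = 0.0104, and adjusted p = 0.824 with an estimated correlation).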

How the results depend on the processing

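All alternatives were chosen before the data were examined, except the list tests with members left out. Bach2 passed in both cell types under every alternative that gave it a value (log2 fold change 3.18 to 3.50 in Tfh and 2.28 to 2.55 in non-Tfh cells), and it has no value where it was left out before normalization. For Bach2 against empty vector in Tfh cells, 196 genes became 736 with no filter, 473 with the replicate number as a block, 313 with DESeq2 and 1 against a 1.5-fold change, where a larger change is asked of each gene. With no filter and with the block all 196 stayed. In non-Tfh cells 100 genes became 332 with no filter, 207 with the block and 8 against a 1.5-fold change. Between Tfh and non-Tfh cells, the 1.5-fold test left 702 of 2515 genes with empty vector and 768 of 2796 with Bach2. The interaction's 0 genes became 37 with no filter, 3 with the block, 70 with a block within each vector and 5 with DESeq2. Deviations of libraries with the same number correlated at 0.208 and 0.240 between Tfh and non-Tfh cells of a vector. They did at -0.00413 to 0.129 in the other 4 pairs of groups. The labels do not pair the numbers, and 2 numbers leave a shared origin open. Except for the 1.5-fold test, the cause of these shifts was not tested. No other scaling, stricter filter, non-robust fit, limma-voom fit, smaller set of groups or omission of genes of other cell types moved a count by over 1.5 times.

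Leaving out 1 library gave 15 to 237 genes for the vector in Tfh cells, 14 to 127 in non-Tfh cells, 1340 to 2688 between cell types with empty vector, 1916 to 2715 with Bach2, and 0 to 1 for the interaction. Fewer libraries widen the errors, and the lone library is assumed to vary like the other groups. With an estimated correlation, called lists fell to 0 for the vector in Tfh cells, 1 in non-Tfh cells, 1 between cell types with empty vector, 0 with Bach2 and 0 for the interaction. With fry they fell to 8 for the vector in Tfh cells, 4 in non-Tfh cells and 0 for the interaction. The plasma cell list in non-Tfh cells, not past the threshold and downward by camera with a positive median (0.57, adjusted p = 0.746), was upward by camera without replicate 2 of the Bach2 group (median 1.32, adjusted p = 0.00544). It had leave-one-out medians from -1.39 to 1.43, since 1 library of that group held most of its plasma cell counts. The correlation of vector effects between cell types, 0.307, was 0.531 with the stricter filter, 0.0281 with no filter, 0.613 over genes called in either and 0.189 to 0.321 with a library left out. That of cell type effects between vectors, 0.843, was 0.926, 0.290 and 0.903 in the same settings, 0.741 by Spearman and 0.761 to 0.831 with a library left out.

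Of the single gene results under the alternatives, 2620 were unchanged, 149 newly past and 204 no longer past the threshold for the vector in Tfh cells, and 2752, 120 and 166 in non-Tfh cells. The counts were 3097, 59 and 125 between cell types with empty vector, 3109, 34 and 119 with Bach2, and 2901, 47 and 0 for the interaction. Among list results, 411 were unchanged, 4 newly past and 62 lost for the vector in Tfh cells, 415, 20 and 41 in non-Tfh cells, 439, 16 and 22 between cell types with empty vector, 410, 13 and 54 with Bach2, and 390, 36 and 51 for the interaction. Under each other scaling the median log2 fold change of all genes stayed within 0.0204 of 0. Depth limits genes near the floor of 0.303 to 0.382 CPM.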

Other observations

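Of the tests here, those on Ighv genes and on Tfh-biased genes were written before their values were seen, and that on other B cell genes was chosen after the result was seen. B cell markers summed to 724 (non-Tfh) and 1200 (Tfh) CPM with empty vector, 714 and 1162 CPM with Bach2, mostly Ighm, Cd22 and Cd37. Cd22 rose in Tfh cells with empty vector from 120 to 211 CPM (0.82, adjusted p = 0.000230). Group sums of MHC class II genes were 94.8 to 98.2, myeloid 346 to 382, stromal 1.93 to 2.52 and erythroid at most 0.501 CPM. CD8 T cell markers summed to 129 (non-Tfh) and 36.3 (Tfh) CPM with empty vector, and 202 and 36.2 CPM with Bach2. By group Cd8a was at most 0.690 and Cd8b1 13.8 to 18.1 CPM, but Klrk1 47.1 and 5.26, then 97.1 and 6.35 CPM. NK and innate lymphoid markers summed to 108 and 82.1, then 126 and 105 CPM. Plasma cell genes held 5.61 to 17.8 CPM by group, and 31.3 CPM in replicate 1 of the Bach2 non-Tfh cells. Only there were Ighg2b (12.2 CPM) and Ighg2c (10.04 CPM) at such levels. The NK receptor gene Klrb1c was higher in Tfh than in non-Tfh cells, from 13.0 to 58.7 CPM with empty vector (2.18, adjusted p = 3.06e-05) and to 89.6 CPM with Bach2 (2.39, adjusted p = 1.12e-05). Ribosomal protein genes summed to 22553 CPM in non-Tfh cells with Bach2 and to 18872 to 19981 CPM in the other groups.

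Lists not past the threshold had these medians for the vector in Tfh and non-Tfh cells. AP-1 and Maf family factors had -0.00 and 0.01, chemokine receptors -0.04 and -0.08, cytokine receptors 0.06 and -0.01, Myc and ribosome biogenesis -0.04 and 0.03, apoptosis 0.02 and -0.01, chromatin modifiers 0.08 and 0.02, T cell identity 0.06 and 0.03 and the dissociation response 0.06 and 0.04. Among these Socs1 fell (-0.60, adjusted p = 0.0198) and Bcl2l11 rose (0.67, adjusted p = 0.0304) in Tfh cells, and Kmt2a rose (0.55, adjusted p = 0.0307) and Il12rb1 fell (-0.67, adjusted p = 0.0153) in non-Tfh cells. Marker lists had -0.28 and 0.27 for B cells, 0.04 and 0.23 for MHC class II, -0.83 and 0.57 for plasma cells (0.03 in Tfh cells with floor genes at their bound), -0.06 in both for myeloid cells and -0.03 and 0.39 for NK cells. In Tfh cells only, the early TCR response (-0.10), the unfolded protein response (-0.08), ribosomal proteins (0.00) and CD8 markers (0.06) were not past, and in non-Tfh cells only, Th2 (-0.49), Treg (0.02), cell cycle inhibitors (0.13), amino acid transport (-0.03), mitochondrially encoded (0.04) and histone genes (-0.09) were not.

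Between Tfh and non-Tfh cells with empty vector and with Bach2, the lists not past either threshold were the naive and memory list (medians -0.33 and 0.03, with 8 rises and 12 falls, then 12 and 11), the early TCR response (0.12 and 0.22), AP-1 factors (0.20 and 0.10), Th2 genes (-0.68 and -1.33), glycolysis (0.15 and 0.04) and oxidative phosphorylation (0.00 and -0.09). Others were cell cycle inhibitors (-0.21 and -0.15), amino acid transport (-0.14 and -0.30), apoptosis (-0.09 in both), heme response (0.05 in both), chromatin modifiers (-0.08 and -0.09), the dissociation response (-0.13 and -0.08) and histone genes (-0.03 and -0.47). Markers of B cells (-0.72 and -1.04), MHC class II (-0.48 and -1.07), plasma (-2.29 and -2.36), myeloid (-0.42 and -0.10) and NK cells (-1.31 and -2.05) were not past either. Camera weighs members by their statistics, and its sign differed from the median in MHC class II and CD8 lists for the vector in Tfh cells, in AP-1, Treg, apoptosis and plasma cell lists in non-Tfh cells, in B cell and MHC class II lists between cell types with empty vector, and in naive, cytokine receptor, glycolysis and B cell lists with Bach2. Mean and median differed in sign in 7 lists for the vector in Tfh cells and in 3 in non-Tfh cells, none of them past the threshold, and in 3 lists between cell types with either vector. The Tfh programme without Cxcr5 and Pdcd1, a test chosen after seeing the data, had 30 rises and 3 falls with a median of 1.19 with empty vector (adjusted p = 0.110 with an estimated correlation).

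Ighm, the immunoglobulin heavy chain gene, was higher in Tfh than in non-Tfh cells, at 755 ± 59.5 against 368 ± 55.3 CPM (SD, n = 4, both vectors; 1.05, SE 0.16, adjusted p = 0.00137 with empty vector). B cell RNA in the Tfh libraries would bring Igkc, Cd79a, Cd79b, Cd74 and Ms4a1 with it, but their sum in Tfh minus that in non-Tfh cells was -24.3 CPM (SE 12.8), which argues against it. That sum was 62.2 and 64.8 CPM in replicate 1 and 22.3 and 19.1 CPM in replicate 2 of the non-Tfh cells (empty vector, then Bach2). Transcripts of Ighm without a rearranged V segment remain a candidate explanation. All 108 Ighv genes together held at most 0.141% of the Ighm CPM in a Tfh library, under the 5% set beforehand. The non-Tfh libraries, at 0.160% to 1.08%, were under it too. Passing this cut therefore does not tell why Ighm was higher in Tfh cells.

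Tigit had the smallest adjusted p of a fall with Bach2 in non-Tfh cells. Fewer Tfh cells in the Bach2 non-Tfh gate would lower genes that are more Tfh-biased than Tigit by at least as much. Their median was -0.0516 (SE over 70 genes 0.286), with 1 of 70 past the threshold, which argues against that explanation. Whether Bach2 acts on Tigit directly was not tested.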
